A study of Rattus norvegicus with 12 samples.

How the data were processed

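RNA sequencing was carried out on 12 libraries of rat cardiac progenitor cells, 3 in each of 4 groups: cells in suspension, cells on fibronectin, cells on laminin and cells on dishes without coating. Per the labels' protocols, dishes were seeded at low density and kept for 2 h in medium with 0.1% fetal bovine serum. The labels carry this protocol for the suspension libraries too, without saying how those cells were handled. Total RNA was collected in TRIzol and made into libraries with the TruSeq Stranded Total RNA LT kit, per the labels' protocols. Each library carries a batch in the labels, and the batch equals the replicate number in every group. The cells derive from a single clone and the submitters describe the libraries as biological triplicates, so p-values measure variation between batches of this line and not between animals. The labels do not say whether a batch is a separate thaw, passage or day.

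The deposited values are raw read counts per gene, 1 file per library, keyed by Entrez gene identifier per the file headers. The unit was checked on the values, which are whole numbers with totals between 15875160 and 20852160 per library. The genome build was rn4, per the submitters' processing notes. The aligner, the counting tool, the annotation release and the strand setting of the counting are not given in the sources used here, so reads from overlapping antisense genes and near-identical copies cannot be judged. Each file held 16924 genes, of which 16761 identifiers matched a symbol in the rat RefSeq table of assembly GRCr8. That table was used for names only, and no coordinates were printed because the builds differ. The other 163 identifiers held between 0.301% and 0.357% of a library's counts and stayed in the tests. Ribosomal RNA genes took between 0.448% and 4.24% of the counts. GC content could not be checked because no genome sequence was at hand.

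Differential expression was tested on the deposited counts with edgeR 4.0.16 in R 4.3.3, using glmQLFit and glmQLFTest. Genes were kept by filterByExpr on the 4 groups, which left 10020 genes, and 3796 genes had no count in any library. Libraries were scaled by TMM, with factors between 0.962 and 1.03. All 12 libraries entered a single means model of 4 groups without a batch term, with 8 residual degrees of freedom, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. A change is a log2 fold change given ± its SE. CPM values are TMM-scaled and computed from the deposited counts and are given as mean ± SD over 3 libraries.

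The labels assign the libraries of a replicate number to a shared batch, so the numbers pair the samples. Deviations of log2 CPM from the group means correlated with a median of 0.409 over the 18 same-batch pairs of libraries and -0.124 over the 36 pairs from different batches, across genes, which are not independent replicates. Among the 9 same-batch pairs of attached libraries the lowest correlation was 0.514. A second fit adds the batch as a block, with 6 residual degrees of freedom. The biological coefficient of variation was 0.152 without the block and 0.100 with it.

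Gene lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and an inter-gene correlation preset at 0.01. Adjustment ran over the 25 lists with at least 4 tested genes of 26 lists fixed in advance. Camera was repeated with the correlation estimated from the data, and fry was run as a second list test. The lists hold YAP and TAZ targets, the Hippo pathway core, Polo-like kinases, SRF and MRTF cytoskeletal targets, immediate early genes, ERK feedback genes, focal adhesion components, extracellular matrix genes, G1/S and replication genes, G2/M genes, p53 targets, TGF-beta and BMP targets, Wnt and Notch targets, NF-kB and cytokine genes, cholesterol synthesis genes, the unfolded protein and integrated stress response, heat shock genes, hypoxia and glycolysis genes, ribosome biogenesis genes, apoptosis genes, and markers of cardiomyocytes, endothelium, smooth muscle, fibroblasts and mesenchyme, blood cells and progenitors. A count of list members adjusted over the list alone uses Benjamini-Hochberg within that list.

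Groups, comparisons, tests, gene lists, the other settings named next and the naming rule were fixed before the data were examined. The rule names the 10 largest rises and 10 largest falls past the threshold, with mean log2 CPM of at least 2 and the same direction in all 3 batches, and 5 of each for the comparisons of fibronectin and laminin with no coating. It skips symbols that begin with LOC, RGD, MGC, Mir or Snor. It adds Yap1, the Polo-like kinases, the YAP and TAZ targets, and the 4 members with the smallest p of each list described. Where fewer than 10 genes qualified in both directions together, the rule turns to the fit with the block. For fibronectin against no coating, qualifying genes were counted before the limit of 5 per direction was applied, so the fit without the block was used. This reading of the rule was settled after the calls were known.

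The other settings fixed in advance were the batch block, DESeq2 size factors, library size without TMM factors, DESeq2 1.42.0, limma-voom, no low count filter, a filter of at least 5 CPM in at least 3 libraries, fits to the groups compared only, a minimum fold change of 1.2, and each library left out in turn, or each batch for the test of any difference. Settings added after the data were seen left out batch 3 in the comparisons of 2 groups, left out batch 3 with the block, left out batch 3 in the attached groups only, used a library score for the deviation of the attached replicate 3 libraries as a covariate, or left out ribosomal RNA genes. The overlap between comparisons that share libraries was set against 20 simulations of unchanged groups, drawn without batch effects. Groups of 3 against 3 were also split in the 10 possible ways, and 100 divisions of the 12 libraries into 4 groups of 3 were used for the test of any difference, with 100 more that keep 1 library of every batch in each group, added after the data were seen.

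The procedure was tested on simulated counts for laminin against suspension over 10020 genes with 200 genes changed. Without batch effects it called 145 genes, 9 of them falsely, and recovered 28.4%, 76.1% and 100% of genes changed 1.5-fold, 2-fold and 4-fold. With batch effects simulated at the size of the blocked fit, it made 141 calls, of which 0 were false, and recovered 34.3%, 79.1% and 98.5%. The fit with the block then made 184 calls, 12 of them false, and recovered 65.7%, 94.0% and 98.5%. These simulated batch effects were equal in all groups. In the data suspension 3 did not share the deviations of the attached replicate 3 libraries (correlation at most 0.0676). The false calls simulated with batch effects therefore do not carry over to comparisons with suspension. Camera called the changed list, at adjusted p = 2.08e-19 by Benjamini-Hochberg, and 0 of the unchanged lists. Genes were drawn independently of one another there, without batch effects. This therefore does not test the preset correlation on lists whose genes vary together. Figures were drawn with matplotlib 3.10.9. Intervals given for ratios of summed counts are 95% intervals that cover counting error only.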

Results

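The transcriptomes of rat cardiac progenitor cells were profiled in suspension and 2 h after plating on fibronectin, on laminin or on uncoated plastic. Fibronectin and laminin are extracellular matrix proteins bound by different sets of integrins. The series title names matrix-dependent fate and the early regulation of YAP, a transcriptional co-activator of the Hippo pathway, and Plk2, a Polo-like kinase. Each group held 3 libraries. Total counts ran from 15875160 in no coating 2 to 20852160 in laminin 2, and each of the other libraries lay between these values. Vim, a mesenchymal intermediate filament gene, was measured at 5125 CPM over the 12 libraries, Col1a1 at 1164 CPM and the cardiac transcription factor Gata4 at 88.3 CPM. The cardiomyocyte genes Nkx2-5 and Myh7 had 0 counts over the 12 libraries, which allows up to 3 counts, and Myh6 had 1 count. Kit, the receptor used to isolate such progenitors, stood at 3.09 CPM. The endothelial list had 3 tested genes and was not tested as a list, with Flt1 at 135 CPM and Pecam1 at 0.273 CPM.

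The first principal component of log2 CPM held 56.1% of the variance and the second 16.2%. Suspension libraries lay between -30.8 and -27.8 on the first component. Replicates 1 and 2 of the attached groups lay between -7.04 and 1.46, whereas fibronectin 3, laminin 3 and no coating 3 lay at 20.8, 35.0 and 41.9. The spread within attached groups was therefore dominated by batch 3, and values with the batch as a block are given where they change a call or move a count by over 1.5 times.

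**Figure D1:**
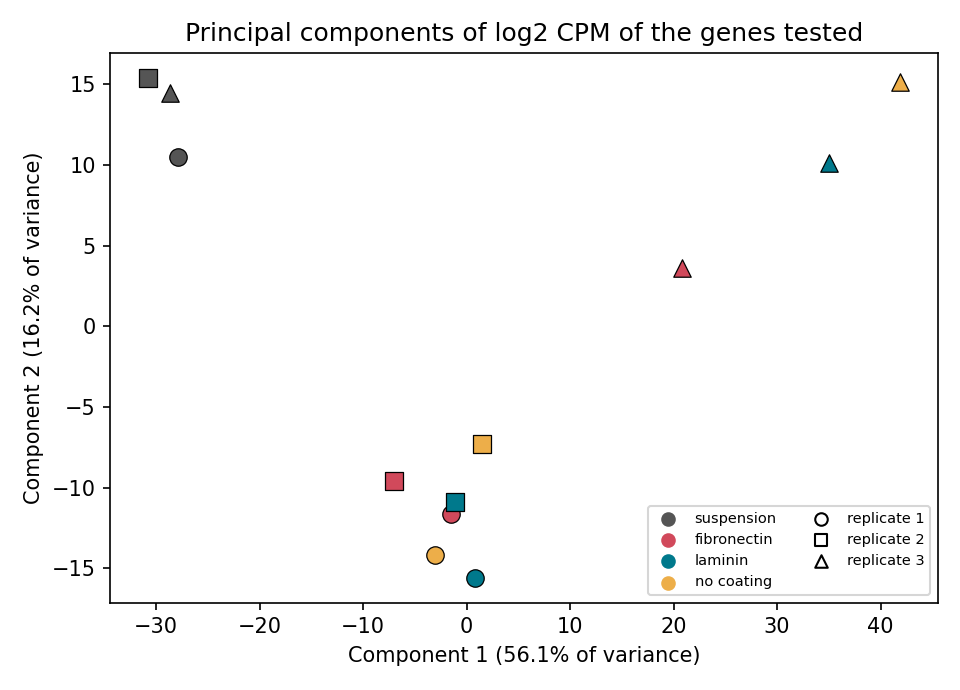
Principal components of log2 CPM over 10020 genes for the 12 libraries, coloured by group, with a marker for each replicate; the axes give component scores. The suspension libraries group at the left and the attached replicate 3 libraries lie apart at the right, from 20.8 to 41.9 on the first component.

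Fibronectin was compared with suspension to find how cells plated on this matrix differed from cells in suspension. The labels carry the plating protocol, 2 h in 0.1% serum, for the suspension libraries too, but do not describe how suspension cells were handled. If their time or serum differed, the comparisons with suspension hold that difference as well. Notch1 (Entrez 25496), a Notch receptor, rose by 2.00 ± 0.11 on the log2 scale, and the Notch target Hey2 (155430) rose by 2.74 ± 0.19, from 3.77 ± 0.35 to 25.3 ± 0.33 CPM (SD, n = 3). Nrarp, a Notch feedback gene, had 1 count over the suspension libraries and 207 over the fibronectin libraries, a ratio of 199 with a counting interval from 35.3 to 7901. Id1 (25261), a BMP-responsive inhibitor of differentiation, fell by 2.36 ± 0.20 from 392 ± 39.4 to 76.5 ± 10.9 CPM, and Id3 (25585) fell by 1.42 ± 0.22. The immediate early gene Egr1 (24330) fell by 2.60 ± 0.38 and the EGF receptor ligand Hbegf (25433) by 2.00 ± 0.28.

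The largest rise named by the rule on fibronectin was that of Cyp1a1 (24296), a target of the aryl hydrocarbon receptor, at 4.83 ± 0.72 on the log2 scale. Adgrg1 (260326), an adhesion G protein-coupled receptor, rose by 2.70 ± 0.12, the calcium-regulated transcription factor Nfatc2 (311658) by 2.64 ± 0.17, Eepd1 by 2.29 ± 0.16, Olfml2a by 2.27 ± 0.16, Mrgprf by 2.21 ± 0.26, Neurl3 by 2.18 ± 0.16, the proprotein convertase Pcsk2 by 2.14 ± 0.30 and Osgin1 by 2.07 ± 0.13. Among the falls were the transcription factors Dlx2 at -2.39 ± 0.22, Mybl1 at -2.00 ± 0.39 and Atoh8 at -1.50 ± 0.21, the growth factor Fgf7 at -1.66 ± 0.30 and the phosphatase gene Dusp1 at -1.40 ± 0.18. Nfkbiz fell by 1.59 ± 0.32, a call that ended when fibronectin 3 was left out.

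Of the 13 Wnt and Notch targets tested on fibronectin, 7 rose and 1 fell, and 7 rose and 2 fell when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.0042; adjusted p = 0.25 with an estimated correlation). Notch1, Nrarp, Hey2 and Jag1 had the smallest p, and these belong to the Notch pathway. The other rises were Hey1, Hes1 and Notch3, also Notch pathway genes, so no Wnt target was called higher. The same 7 genes made up the rises of this list on laminin and on uncoated dishes. Of 13 TGF-beta and BMP targets, 5 fell and 0 rose, and 8 fell and 1 rose when adjusted over the list alone (camera, adjusted p = 0.00216; adjusted p = 0.25 with an estimated correlation). Smad7, an inhibitor of TGF-beta signalling, fell by 1.06 ± 0.09 and Id4 by 1.02 ± 0.11. The ERK feedback genes, with 4 of 15 down (camera, adjusted p = 0.0042; adjusted p = 0.441 with an estimated correlation), and the Hippo pathway core, with Vgll4 down of 14 (camera, adjusted p = 0.0128; adjusted p = 0.441 with an estimated correlation), also passed. Over the list alone the counts were again 4 and 1. The G2/M list passed as lower (camera, adjusted p = 0.013; adjusted p = 0.25 with an estimated correlation) with 0 of 20 members called by edgeR, by either adjustment, 7 down with the block and 11 down without batch 3. With the block 5 members of the Hippo core, 8 TGF-beta and BMP targets and 7 YAP and TAZ targets were down, and without batch 3 the Hippo core had 4 down. The blood cell marker list passed as higher (camera, adjusted p = 0.013; adjusted p = 0.342 with an estimated correlation), with Cd14 and Laptm5 up of 4 by either adjustment (Laptm5 without suspension 2, suspension 3, fibronectin 1 or fibronectin 3 did not pass). The leukocyte gene Ptprc had 3 counts over all 12 libraries. Without batch 3 the blood cell and ERK feedback lists no longer passed (camera, adjusted p = 0.117 and 0.179), with 1 and 0 members called.

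Of the 17 YAP and TAZ targets, 2 rose and 2 fell on fibronectin relative to suspension, and 2 rose and 5 fell when adjusted over the list alone (camera, adjusted p = 0.321). Amotl2 (65157) rose by 0.71 ± 0.10 and Fjx1 by 0.91 ± 0.17, while Ankrd1 (27064) fell by 1.98 ± 0.23. Ccn2 (64032) fell by 0.80 ± 0.21 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.0379), a call lost when any of suspension 1, 2 or 3, fibronectin 2 or fibronectin 3 was left out, with adjusted p up to 0.149. Ccn1 (83476) changed by 0.12 ± 0.31 (edgeR, Benjamini-Hochberg adjusted p = 0.827), Plk2 (83722) by 0.11 ± 0.15 (edgeR, adjusted p = 0.675) and Yap1 (363014) by -0.14 ± 0.06 (edgeR, adjusted p = 0.191), so none of these passed the test. Plk3, another Polo-like kinase gene, fell by 0.47 ± 0.13 (edgeR, adjusted p = 0.0485), a call lost without suspension 1, 2 or 3, fibronectin 1 or fibronectin 2. Without batch 3 the calls of Plk3 and Ccn2 also ended, at -0.58 ± 0.16 and -0.88 ± 0.27 (edgeR, adjusted p = 0.0546 and 0.0742).

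In all, 969 of 10020 genes differed between fibronectin and suspension by edgeR quasi-likelihood at the Benjamini-Hochberg threshold, 662 higher and 307 lower, and all 969 had the same direction in each of the 3 batches. At least 2-fold changes numbered 131 higher and 49 lower. With the batch as a block 2872 genes passed, 1664 higher and 1208 lower. The block takes a batch shift as equal in all groups, and suspension 3 did not share that of the attached replicate 3 libraries. The error of blocked comparisons with suspension may therefore be understated. The share of calls that were higher was 68.3%, 53.9% with library size only (384 higher, 329 lower) and 46.5% without batch 3 (432 higher, 497 lower). Leaving out suspension 2, suspension 3, fibronectin 1 or fibronectin 3 gave 465, 412, 468 and 438 genes.

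Laminin was compared with suspension to ask the same question for the other matrix. Ccn1, a matricellular YAP and TAZ target, fell by 3.23 ± 0.34 from 525 ± 78.2 to 56.0 ± 22.6 CPM (SD, n = 3), and Ccn2, also matricellular, fell by 2.84 ± 0.23 from 673 ± 86.0 to 93.7 ± 22.5 CPM. Plk2 fell by 1.63 ± 0.16 from 49.4 ± 11.9 to 16 ± 1.65 CPM (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 9.02e-05). Notch1 rose by 2.18 ± 0.11 and Hey2 by 2.51 ± 0.18, and Nrarp had 277 counts on laminin against 1 in suspension, a ratio of 262 with a counting interval from 46.6 to 10377. Nlrp3 (287362), an inflammasome sensor, fell by 3.04 ± 0.20, and Sgk1 (29517), a serum- and glucocorticoid-regulated kinase, fell by 2.13 ± 0.11.

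Of 17 YAP and TAZ targets, 9 fell and 1 rose on laminin, and 12 fell and 1 rose when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 3.24e-06; adjusted p = 0.165 with an estimated correlation). Ankrd1 fell by 3.56 ± 0.27, Nuak2 (289419) by 1.40 ± 0.11, Amotl2 by 0.71 ± 0.10 and the Hippo kinase gene Lats2 by 0.77 ± 0.08, whereas Fjx1 rose by 0.93 ± 0.17. Yap1 changed by -0.19 ± 0.06 and did not pass (edgeR, Benjamini-Hochberg adjusted p = 0.0643), but passed with the block (edgeR, adjusted p = 0.0237). The Hippo core list had 4 of 14 down and 6 when adjusted over the list alone (camera, adjusted p = 0.004; adjusted p = 0.363 with an estimated correlation). Of the 4 Polo-like kinases, Plk2 and Plk3 fell, and 3 fell when adjusted over the list alone (camera, adjusted p = 0.00873; adjusted p = 0.165 with an estimated correlation). The call of Plk3, at -0.41 ± 0.13, ended when any single suspension or laminin library was left out. It also ended without batch 3, at -0.47 ± 0.16 (edgeR, adjusted p = 0.0685).

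Of 13 Wnt and Notch targets, 7 rose and 1 fell by either adjustment (camera, adjusted p = 0.004; adjusted p = 0.165 with an estimated correlation), and of 13 TGF-beta and BMP targets 5 fell and 1 rose, 7 and 1 when adjusted over the list alone (camera, adjusted p = 0.00726; adjusted p = 0.191 with an estimated correlation). Smad7 fell by 1.18 ± 0.09, Id1 by 1.83 ± 0.20, Smad6 by 0.94 ± 0.15 and Id4 by 0.62 ± 0.11. ERK feedback genes had 4 of 15 down and 5 when adjusted over the list alone (camera, adjusted p = 0.00418; adjusted p = 0.37 with an estimated correlation), among them the ephrin receptor gene Epha2 at -1.85 ± 0.19 and Spry2 at -0.69 ± 0.13. G2/M genes had 2 of 20 down, 1 when adjusted over the list alone, 12 with the block and 11 without batch 3 (camera, adjusted p = 0.00628; adjusted p = 0.165 with an estimated correlation). Cholesterol synthesis genes did not pass (camera, adjusted p = 0.0883) but passed as lower with the block (camera, adjusted p = 0.0151; adjusted p = 0.600 with both the block and an estimated correlation). Without batch 3 the ERK feedback list no longer passed, with 3 down and 1 up (camera, adjusted p = 0.0672) and the extracellular matrix list passed as lower (camera, adjusted p = 0.0333).

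Further rises named by the rule on laminin were Cyp1a1 at 5.31 ± 0.70, Adgrg1 at 2.92 ± 0.12, Nfatc2 at 2.75 ± 0.17, Olfml2a at 2.56 ± 0.16, Eepd1 at 2.53 ± 0.15, Pcsk2 at 2.50 ± 0.30, Neurl3 at 2.48 ± 0.16, Mrgprf at 2.38 ± 0.26 and the intracellular peptidoglycan receptor gene Nod1 at 2.21 ± 0.11. Further falls were Hbegf at -3.08 ± 0.30, Egr1 at -2.41 ± 0.38, Vof16 at -2.25 ± 0.35, Mybl1 at -2.24 ± 0.40, Dlx2 at -2.22 ± 0.22 and the ephrin gene Efnb2 at -1.97 ± 0.14. In all, 1905 genes differed by edgeR quasi-likelihood with Benjamini-Hochberg adjustment, 1208 higher and 697 lower, and 1904 of them had the same direction in every batch. At least 2-fold changes numbered 147 higher and 100 lower, and the fit with the block called 4333 genes, 2246 higher and 2087 lower. Of the calls 63.4% were higher, 54.8% with library size only (802 higher, 661 lower) and 45.4% without batch 3 (859 higher, 1035 lower). Leaving out suspension 2, suspension 3, laminin 2 or laminin 3 gave 907, 797, 1264 and 1115 genes.

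Uncoated dishes were compared with suspension as plated cells without added matrix. The YAP and TAZ targets Ccn2 and Ccn1 fell by 2.96 ± 0.23 and 2.70 ± 0.34, to 86.7 ± 14.1 and 80.9 ± 29.8 CPM (SD, n = 3), and Ankrd1 fell by 3.96 ± 0.28. Plk2 fell by 1.74 ± 0.16 to 14.8 ± 1.06 CPM (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 6.41e-05). Notch1 rose by 2.43 ± 0.11, from 50.1 ± 3.01 to 271 ± 12.9 CPM, and Hey2 rose by 2.33 ± 0.18. Nrarp had 289 counts against 1 in suspension, a ratio of 300 with a counting interval from 53.5 to 11902. Nlrp3 fell by 3.09 ± 0.20, Hbegf by 2.79 ± 0.29 and Sgk1 by 2.23 ± 0.11.

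On uncoated dishes 6 of 17 YAP and TAZ targets fell and 1 rose, and 12 fell and 1 rose when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 4.84e-06; adjusted p = 0.127 with an estimated correlation). Nuak2 fell by 1.60 ± 0.11, Amotl2 by 0.60 ± 0.10 and Lats2 by 0.52 ± 0.08, and Fjx1 rose by 0.78 ± 0.17, a call lost in a fit to these 2 groups only. Yap1 changed by -0.14 ± 0.06 and did not pass (edgeR, Benjamini-Hochberg adjusted p = 0.165). Of the Polo-like kinases, Plk2 fell of 4 by either adjustment, with 4 down with the block and 3 down without batch 3 (camera, adjusted p = 0.00987; adjusted p = 0.127 with an estimated correlation). The Hippo core had 1 of 14 down, 2 when adjusted over the list alone, 7 with the block and 4 without batch 3 (camera, adjusted p = 0.00676; adjusted p = 0.348 with an estimated correlation). Wnt and Notch targets had 7 of 13 up and 1 down by either adjustment (camera, adjusted p = 0.00221; adjusted p = 0.127 with an estimated correlation), and TGF-beta and BMP targets 5 of 13 down and 1 up, 6 and 1 when adjusted over the list alone (camera, adjusted p = 0.00452; adjusted p = 0.127 with an estimated correlation). Smad7 fell by 1.03 ± 0.09, Id1 by 1.90 ± 0.20, Smad6 by 1.01 ± 0.15 and Id4 by 0.72 ± 0.11.

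ERK feedback genes had 5 of 15 down on uncoated dishes and 7 when adjusted over the list alone (camera, adjusted p = 0.00452; adjusted p = 0.348 with an estimated correlation), with Epha2 at -1.56 ± 0.19. G2/M genes passed as lower with 0 of 20 members called by edgeR by either adjustment, 11 down with the block and 10 down without batch 3 (camera, adjusted p = 0.00953; adjusted p = 0.127 with an estimated correlation). Blood cell markers passed as higher with 2 of 4 members up by either adjustment, Cd14 at 0.54 ± 0.07 and Laptm5 at 0.91 ± 0.21 (camera, adjusted p = 0.00987; adjusted p = 0.229 with an estimated correlation). The call of Laptm5 ended without suspension 2, suspension 3, no coating 1 or no coating 3. Cholesterol synthesis genes passed as lower, with 0 of 18 members called when adjusted over the list alone (camera, adjusted p = 0.0466; adjusted p = 0.722 with an estimated correlation). Without batch 3 the blood cell, cholesterol and ERK feedback lists no longer passed (camera, adjusted p = 0.0700, 0.150 and 0.0816). The blood cell list then had 1 member up, and the ERK feedback list 1 down and 1 up.

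Other rises named by the rule on uncoated dishes were Cyp1a1 at 5.11 ± 0.71, Adgrg1 at 2.99 ± 0.12, Nfatc2 at 2.89 ± 0.17, Olfml2a at 2.71 ± 0.16, Neurl3 at 2.41 ± 0.16, Pcsk2 at 2.33 ± 0.30, Eepd1 at 2.28 ± 0.16 and Mrgprf at 2.25 ± 0.26. Other falls were Mybl1 at -2.27 ± 0.40, Fgf7 at -2.10 ± 0.31, Egr1 at -2.05 ± 0.38, Dlx2 at -1.97 ± 0.22 and Vof16 at -1.93 ± 0.35. By edgeR quasi-likelihood with Benjamini-Hochberg adjustment 1261 genes differed, 850 higher and 411 lower, of which 1258 had the same direction in every batch, and 142 were at least 2-fold higher and 87 at least 2-fold lower. With the block 3889 genes passed, 2014 higher and 1875 lower. The share of higher calls was 67.4%, 54.3% with library size only (496 higher, 417 lower) and 43.1% without batch 3 (519 higher, 684 lower). Leaving out suspension 2, suspension 3, no coating 2 or no coating 3 gave 567, 537, 779 and 644 genes. The fit to these 2 groups only gave 461.

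**Figure D2:**
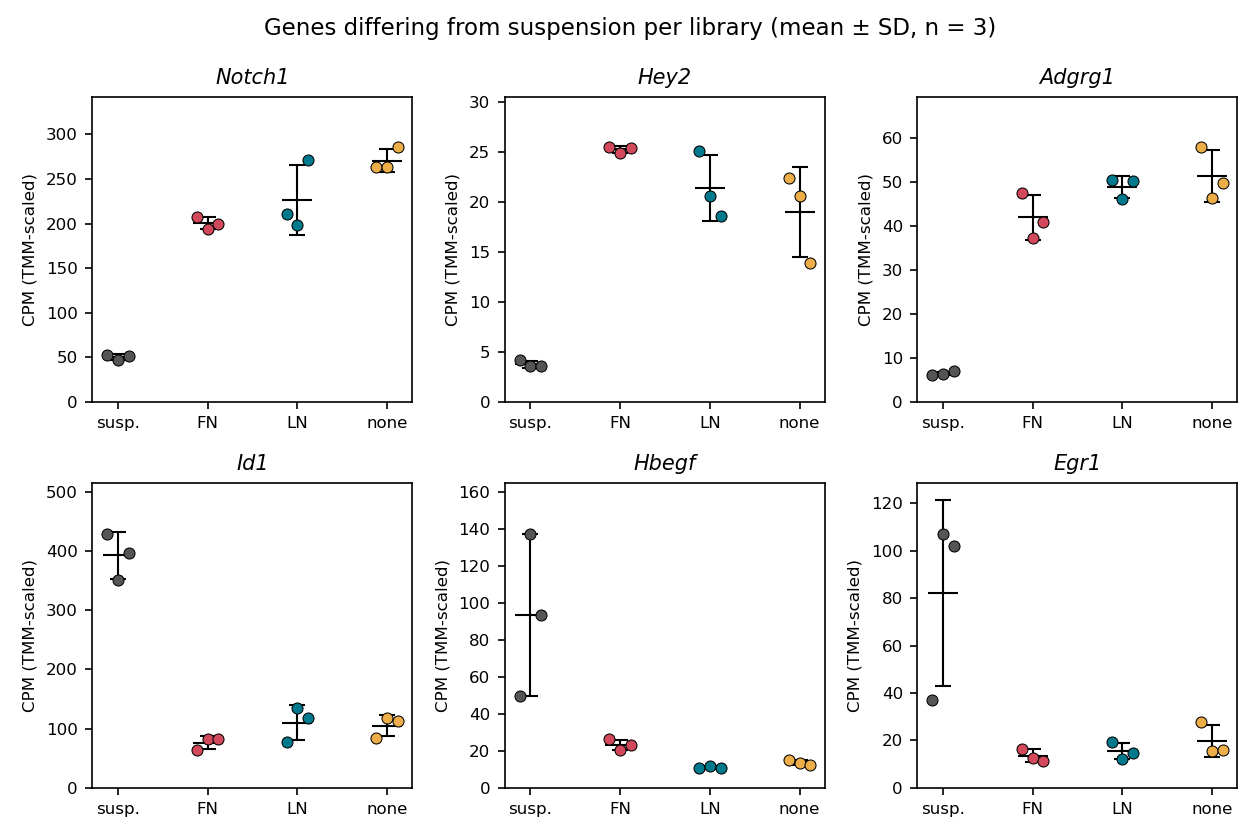
TMM-scaled CPM of 6 genes in each library of cells in suspension (susp.), on fibronectin (FN), on laminin (LN) and on uncoated dishes (none); points are libraries and bars the mean ± SD of 3. Notch1, Hey2 and Adgrg1 lie higher, and Id1, Hbegf and Egr1 lower, in each attached group than in suspension.

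The comparisons with suspension shared 764 calls in all 3, of which 541 were higher and 223 lower. Notch1, Hey2, Adgrg1, Nfatc2, Id1, Egr1 and Hbegf were among the genes called in the same direction on each surface. With the block 2411 genes were shared. Independent lists would share 6.77 higher and 0.876 lower genes. Simulated unchanged groups, with the suspension libraries also drawn anew around the mean suspension levels, shared 0.05 on average and 1 at most. No gene was changed in the simulations, so few could be called in any comparison. Their shared counts therefore cannot show how much overlap shared controls create among many calls. The log2 fold changes correlated across genes with a mean of 0.927 against 0.500 in the simulations, and their covariance was 0.184 against 0.0251, a difference of 0.159. The 3 suspension libraries were too few to split, so part of the excess may come from the shared controls. The simulations also hold no batch effects, whereas attached libraries of the same batch shared deviations (lowest correlation 0.514). Part of the excess may come from these too. A test of any difference among the 4 groups called 969 genes by edgeR with Benjamini-Hochberg adjustment, 3190 with the block, and 177 and 114 when batch 1 or batch 2 was left out.

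Laminin was compared with fibronectin to find what the choice of matrix changed. The largest called difference was in Ccn1, lower on laminin by -3.35 ± 0.35 on the log2 scale, at 56.0 ± 22.6 against 571 ± 115 CPM (SD, n = 3). Ccn2 was lower by -2.04 ± 0.22, Amotl2 by -1.42 ± 0.10 and Nuak2 by -1.42 ± 0.11, and the LIM protein gene Ajuba (85265) by -1.41 ± 0.11. Plk2 was lower by -1.73 ± 0.16, at 16 ± 1.65 against 53.2 ± 4.15 CPM (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.000848), and Nlrp3 by -1.89 ± 0.20. Yap1 itself differed by -0.05 ± 0.06 and did not pass the test.

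Of the 17 YAP and TAZ targets, 4 were lower on laminin and 0 higher, and 7 were lower when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 1.6e-20; adjusted p = 0.0198 with an estimated correlation, and 0.169 with both the block and an estimated correlation). Ccn2 lost its call in a fit to these 2 groups only. Cholesterol synthesis genes were lower as a list (camera, adjusted p = 3.49e-10; adjusted p = 0.348 with an estimated correlation) with 0 of 18 members past the threshold over all genes by edgeR, 5 when adjusted over the list alone and 4 with the block. The SRF and MRTF targets had 0 of 16 members called and 3 over the list alone (camera, adjusted p = 0.000153; adjusted p = 0.348 with an estimated correlation). Immediate early genes had 0 of 25 called, and 3 lower and 1 higher over the list alone (camera, adjusted p = 0.00597; adjusted p = 0.459 with an estimated correlation). The p53 targets passed as lower with Plk2, also a member of that list, as the call of 14 and 2 over the list alone (camera, adjusted p = 0.0149; adjusted p = 0.451 with an estimated correlation), and the Polo-like kinases with Plk2 of 4 by either adjustment (camera, adjusted p = 0.0149; adjusted p = 0.246 with an estimated correlation; adjusted p = 0.0734 with the block).

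The progenitor marker list was lower on laminin with 0 of 6 members called and 1 over the list alone (camera, adjusted p = 0.00777; adjusted p = 0.249 with an estimated correlation). Extracellular matrix genes were lower with 0 of 16 called by either adjustment (camera, adjusted p = 0.0378; adjusted p = 0.459 with an estimated correlation), and hypoxia and glycolysis genes higher with 0 of 17 called by either adjustment (camera, adjusted p = 0.0344; adjusted p = 0.368 with an estimated correlation). Without batch 3 the hypoxia, Polo-like kinase and progenitor lists no longer passed (camera, adjusted p = 0.0601, 0.0767 and 0.0511), and the Hippo core passed as lower (camera, adjusted p = 0.00776). By edgeR quasi-likelihood with Benjamini-Hochberg adjustment 15 genes differed, 1 higher and 14 lower, each with the same direction in every batch, and 9 of them were at least 2-fold lower. Gem (297902), a small GTPase gene, was the higher gene at 0.84 ± 0.12, and the stress-inducible Gadd45b, the kinase gene Pim3 and Metrnl were lower by -1.23 ± 0.18, -0.93 ± 0.13 and -0.86 ± 0.11. These 4 calls ended when fibronectin 1, fibronectin 3 or laminin 1 was left out, and further calls ended without fibronectin 2 (Gem), laminin 2 (Gadd45b, Pim3 and Metrnl) or laminin 3 (Gem and Gadd45b). Without batch 3 the calls of Gem, Gadd45b and Metrnl also ended (edgeR, adjusted p = 0.166, 0.0836 and 0.0511). With the block 41 genes differed, 4 higher and 37 lower. DESeq2 called 44 and the fit to these 2 groups 9, and leaving out fibronectin 1, fibronectin 3, laminin 1 or laminin 2 gave 8, 7, 7 and 8.

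**Figure D3:**
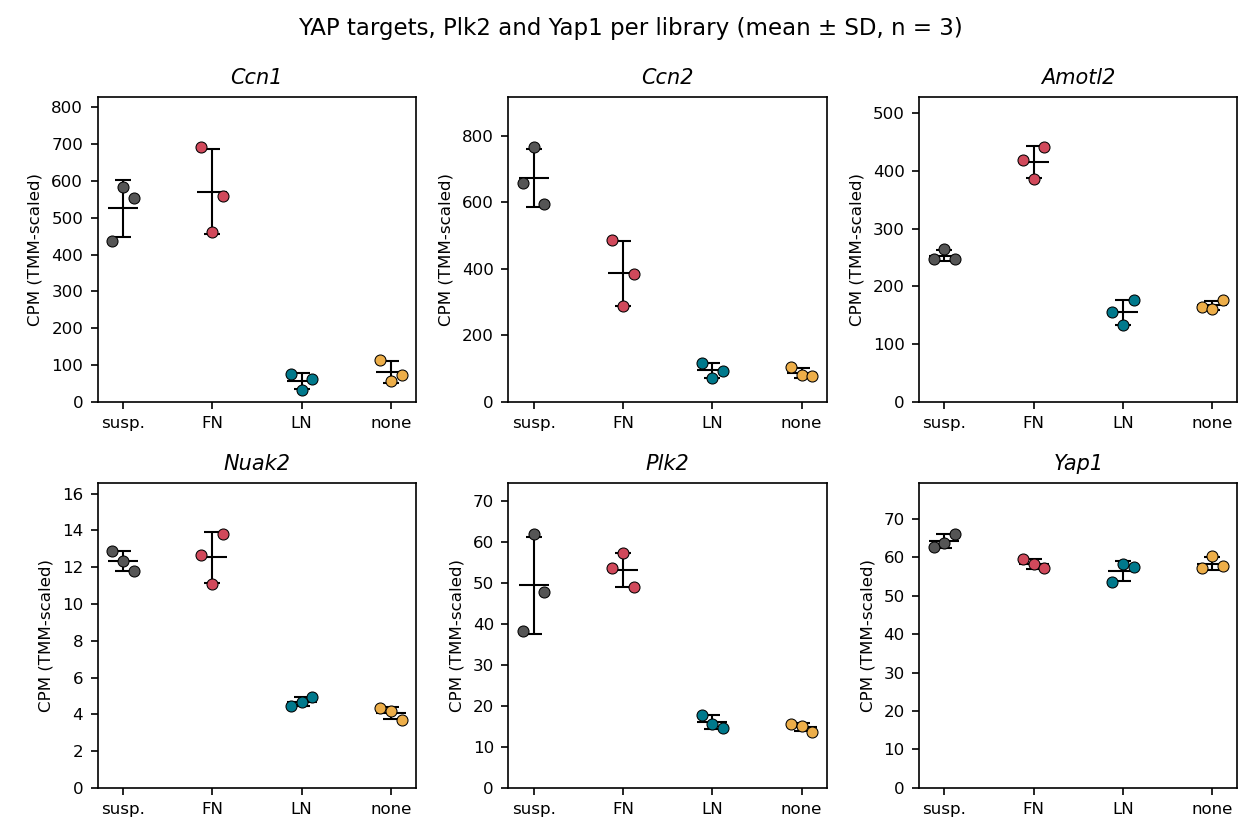
TMM-scaled CPM of 5 YAP targets and Polo-like kinase genes and of Yap1 in each library of cells in suspension (susp.), on fibronectin (FN), on laminin (LN) and on uncoated dishes (none); points are libraries and bars the mean ± SD of 3. For Ccn1, Ccn2, Amotl2, Nuak2 and Plk2 every fibronectin library lies above every laminin and uncoated library, whereas Yap1 lies between 56.4 and 64.2 CPM in the group means.

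Fibronectin was compared with uncoated dishes to separate the coating from plating itself. Ccn1 was higher on fibronectin by 2.82 ± 0.34 and Ccn2 by 2.15 ± 0.22, at 386 ± 98.3 against 86.7 ± 14.1 CPM (SD, n = 3). Plk2 was higher by 1.84 ± 0.16, at 53.2 ± 4.15 against 14.8 ± 1.06 CPM (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.000488). Nuak2 was higher by 1.62 ± 0.11, Amotl2 by 1.31 ± 0.10, Nlrp3 by 1.94 ± 0.21 and Klf2, a flow-responsive transcription factor, by 1.21 ± 0.15. Gem was lower by -0.79 ± 0.12, and Yap1 differed by -0.0016 ± 0.064, which did not pass.

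Of the 17 YAP and TAZ targets, 5 were higher on fibronectin than on uncoated dishes and 0 lower, and 6 were higher when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 2.31e-17; adjusted p = 0.0337 with an estimated correlation, and 0.177 with both the block and an estimated correlation). The fifth called member, Ankrd1, was higher by 1.99 ± 0.31 at 2.60 ± 0.53 against 0.647 ± 0.20 CPM, and its call ended without fibronectin 1, fibronectin 2 or any single no coating library. Cholesterol synthesis genes were higher as a list (camera, adjusted p = 1.45e-10; adjusted p = 0.319 with an estimated correlation) with 0 of 18 members past the threshold over all genes by edgeR, 5 over the list alone and 4 with the block. SRF and MRTF targets had 0 of 16 called and 1 over the list alone (camera, adjusted p = 0.00627; adjusted p = 0.386 with an estimated correlation), and progenitor markers 0 of 6 by either adjustment (camera, adjusted p = 0.00537; adjusted p = 0.271 with an estimated correlation). The p53 targets passed as higher with Plk2 as the call of 14 by either adjustment (camera, adjusted p = 0.0459; adjusted p = 0.422 with an estimated correlation), and hypoxia and glycolysis genes as lower with 0 of 17 called by either adjustment (camera, adjusted p = 0.0387; adjusted p = 0.319 with an estimated correlation). Without batch 3 the hypoxia and p53 lists no longer passed (camera, adjusted p = 0.117 and 0.0543).

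By edgeR quasi-likelihood with Benjamini-Hochberg adjustment 18 genes differed between fibronectin and uncoated dishes, 17 higher and 1 lower, all in the same direction in every batch, and 11 were at least 2-fold higher. With the block 47 passed, 39 higher and 8 lower. DESeq2 called 53, the fit to these 2 groups 11, and leaving out no coating 1 gave 10. Without batch 3 there were 11, all higher on fibronectin. The calls of Ccn1 at 2.75 ± 0.44, Ankrd1 at 2.43 ± 0.38 and Gem at -0.84 ± 0.16 ended (edgeR, adjusted p = 0.0947, 0.0929 and 0.223). Klf2 lost its call without no coating 1 or no coating 2, and Gem without any of fibronectin 1, 2 or 3, no coating 1 or no coating 3. The differences of fibronectin from laminin and from uncoated dishes shared 15 calls, 14 higher on fibronectin and 1 lower, and 32 with the block, 29 higher and 3 lower. For the 15, independent lists would share 0.0238 and 9.98e-05 and simulated unchanged groups shared 0. With no gene changed there, few calls could arise to be shared, so that count sets no level for the overlap. The 3 fibronectin libraries enter both differences and were too few to split. Across genes these differences correlated at 0.679 against 0.497 in simulations, with a covariance of 0.0234 against 0.0249. The simulations hold no batch effects, which partly cancel between surfaces of the same batch, so these simulated values set no firm level for unchanged groups.

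Laminin was compared with uncoated dishes to ask what this coating added. Plk2 differed by 0.11 ± 0.16, Ccn1 by -0.53 ± 0.32, Ccn2 by 0.11 ± 0.21, Amotl2 by -0.11 ± 0.10, Nuak2 by 0.20 ± 0.12, Ankrd1 by 0.40 ± 0.37 and Yap1 by -0.05 ± 0.06, and none passed the test. By edgeR quasi-likelihood with Benjamini-Hochberg adjustment 0 genes differed, with 156 at an unadjusted p under 0.05. The fit with the block gave 0 with 361 unadjusted, and DESeq2 and limma-voom each gave 0. With both batch 3 left out and the block, 28 genes passed. Extracellular matrix genes were lower on laminin as a list with 0 of 16 called by either adjustment (camera, adjusted p = 0.0153; adjusted p = 0.98 with an estimated correlation). Cardiomyocyte markers were lower with 0 of 5 called by either adjustment (camera, adjusted p = 0.0464; adjusted p = 0.454 with an estimated correlation; adjusted p = 0.167 without batch 3), and without batch 3 the Hippo core also passed as lower (camera, adjusted p = 0.0109).

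In none of the 6 comparisons did camera with the preset correlation call the lists of focal adhesion components, G1/S and replication genes, NF-kB and cytokine genes, heat shock genes, ribosome biogenesis genes, apoptosis genes, the unfolded protein and integrated stress response, smooth muscle markers, or fibroblast and mesenchymal markers. Some of their members passed: Csf1, a macrophage growth factor, fell by 1.26 ± 0.10, 1.28 ± 0.10 and 1.14 ± 0.10 on fibronectin, laminin and uncoated dishes, and the pro-apoptotic gene Bmf rose by 0.78 ± 0.14, 1.30 ± 0.14 and 1.05 ± 0.14. Tnnt2, a troponin gene of the cardiomyocyte list, rose by 1.39 ± 0.19, 1.56 ± 0.18 and 1.60 ± 0.18, from 1.80 ± 0.23 CPM in suspension to 4.74 ± 0.91, 5.32 ± 0.32 and 5.46 ± 0.89 CPM. Members of the hypoxia and glycolysis list went both ways, with Ndrg1 up by 1.34 ± 0.08, 1.51 ± 0.08 and 1.28 ± 0.08, and Vegfa down by -1.03 ± 0.08, -0.86 ± 0.08 and -0.76 ± 0.08.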

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

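The differences between the surfaces were tested as planned, and the tests that weigh explanations for them were chosen after the result was seen, as were Gata3, Sgk1, Fam107b and Rhob, which the naming rule does not give here.

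For 15 genes expression differed between fibronectin and laminin, and also between fibronectin and uncoated dishes, by edgeR quasi-likelihood at the Benjamini-Hochberg threshold. The suspension level cancels in these differences. On the log2 scale the value on fibronectin minus that on laminin was 3.35 for Ccn1, 2.04 for Ccn2, 1.89 for Nlrp3, 1.73 for Plk2, 1.42 for Amotl2, 1.42 for Nuak2, 1.41 for Ajuba, 1.28 for Gata3, 1.23 for Gadd45b, 0.93 for Pim3, 0.86 for Metrnl, 0.79 for Sgk1, 0.74 for Rhob, 0.59 for Fam107b and -0.84 for Gem.

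The pattern weighed here is the higher level of Ccn1, Ccn2, Amotl2, Nuak2 and Plk2 on fibronectin than on laminin and uncoated dishes, and of Ankrd1 than on uncoated dishes, since Ankrd1 did not pass against laminin. With any of the 9 attached libraries left out, at least 83.3% of the calls of these genes in its comparisons were kept. These were 10 of 11 without fibronectin 1 or 2 and 5 of 6 without any no coating library, the lost call being that of Ankrd1. Apart from Ankrd1, the calls thus did not rest on any single attached library. The genes were chosen because they passed with all libraries, so their kept calls cannot decide whether a library was mislabelled. Library scaling is argued against, since 11 of the 11 calls of these genes were kept with library size only. The attached replicate 3 libraries are argued against as the whole source, since 9 of the 11 calls were kept without batch 3 and 11 with the block added. Ccn1 and Ankrd1 against uncoated dishes went from 2.82 ± 0.34 and 1.99 ± 0.31 to 2.75 ± 0.44 and 2.43 ± 0.38. Their calls ended with fewer libraries and a larger SE. The calls depended more on the other batches. Of the YAP and TAZ targets and Plk2, the blocked fit without batch 1 called only Ccn1 and Plk2 higher on fibronectin than on either other surface. It called 5 without batch 2 (Ccn1, Ccn2, Amotl2, Nuak2 and Plk2) and 9 without batch 3. In the batch left out, each of these genes was higher on fibronectin than on both other surfaces. A difference in YAP and TAZ activity between the coatings was not tested apart from these genes, and no protein or localisation of YAP was measured.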

How the results depend on the processing

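The alternatives that left out batch 3 (other than for any difference without the block, where each batch was left out as planned) or ribosomal RNA genes, used the library score, or joined the block to an estimated correlation were chosen after the data were seen; the rest were planned. Of 172 alternative values of counts, 96 lay within 1.5 times. The cause of the moves below was not tested unless stated.

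With the replicate block the counts of genes against suspension were 2872 (fibronectin), 4333 (laminin) and 3889 (no coating). They were 41 for laminin against fibronectin, 47 for fibronectin against no coating and 3190 for any difference. The comparisons with suspension then shared 2411 genes. The biological coefficient of variation was 0.152 without the block and 0.100 with it. Attached libraries of the same batch shared deviations, with a lowest correlation of 0.514. The block changed no call of a named gene or list other than those given with the comparisons. The block takes a batch shift as equal in all groups, which suspension 3 did not share, so its counts against suspension may rest on too small an error. DESeq2 gave 44, 53 and 1650 for laminin against fibronectin, fibronectin against no coating and any difference. A minimum fold change of 1.2, which asks more of each gene, gave 301, 465 and 346 against suspension and 9 for laminin against fibronectin. Fits to the 2 groups compared, with fewer samples, gave 461 for no coating against suspension, 9 for laminin against fibronectin and 11 for fibronectin against no coating. With a library left out, counts ran from 412 to 720 (fibronectin), 797 to 1439 (laminin) and 537 to 1285 (no coating) against suspension, 7 to 15 for laminin against fibronectin, 10 to 14 for fibronectin against no coating and 0 to 0 for laminin against no coating, again with fewer samples. For any difference a whole batch of 4 libraries was left out at a time, and counts ran from 114 to 945.

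Batch 3 left out in all groups gave 11 for fibronectin against no coating. Together with the block it gave 2812, 4001 and 3073 against suspension, 134, 90 and 28 for the comparisons between surfaces and 3191 for any difference. Batch 3 left out in the attached groups gave 1833, 3038 and 2133 against suspension, 26 for laminin against fibronectin and 2212 for any difference. The library score as a covariate gave 2370 and 1929 for fibronectin and no coating against suspension, 68 and 75 for laminin against fibronectin and fibronectin against no coating, and 1969 for any difference. With the block it gave 3055, 3160 and 2063 against suspension, 240, 203 and 10 between surfaces and 2596 for any difference. The score was estimated from the same counts, and suspension lay below every attached library on it, so its calls carry no error control.

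Lists passing camera numbered 6, 7 and 9 against suspension, 9 and 6 for fibronectin against laminin and no coating, and 2 for laminin against no coating. With an estimated correlation they numbered 0, 0, 0, 1, 1 and 0, and with the block added 0 in each. By fry they numbered 2, 2 and 0 in the comparisons between surfaces; fry does not compare a list with other genes.

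Of 5307 values of 253 gene results under alternatives, 4770 kept their direction and side of the threshold, 516 no longer passed, 9 newly passed and 12 changed sign, none of them a called value. Yap1 in fibronectin against no coating, at -0.0016, was 0.0081 with DESeq2 size factors, 0.0090 without a low count filter, 0.0081 with DESeq2, 0.0070 without batch 3, 0.0071 with the block added, 0.012 without batch 3 in the attached groups and 0.00047 without ribosomal RNA genes, and with a library left out it ran from -0.0182 to 0.0218, with 0.0118 without fibronectin 3 and the highest without no coating 2. With a library left out, Plk2 in fibronectin against suspension ran from -0.0453 (without suspension 1) to 0.304, Ccn1 in the same comparison from -0.0413 (without fibronectin 1) to 0.252, and Ccn2 in laminin against no coating from -0.0807 (without laminin 1) to 0.269. Totals of 15875160 to 20852160 counts limit genes of few counts, such as Nrarp and Hey1 in suspension, whose ratios rest on 1 and 3 counts.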

Other observations

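The lists of aryl hydrocarbon receptor, NRF2 and Notch pathway genes, the tests of the replicate 3 libraries and of the split of calls, and the divisions within batches, were chosen after the results were seen; the counts of other splits of the libraries were planned.

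Several xenobiotic response genes were higher in attached cells than in suspension. Cyp1b1, a cytochrome P450 gene, rose by 1.79 ± 0.21, 1.97 ± 0.21 and 1.97 ± 0.21 on fibronectin, laminin and uncoated dishes, from 207 CPM in suspension to 716, 814 and 813 CPM. Ahrr, the repressor of the aryl hydrocarbon receptor, rose by 1.39 ± 0.13, 1.34 ± 0.13 and 1.35 ± 0.13, and Nqo1, a target of both this receptor and NRF2, by 1.28 ± 0.20, 1.47 ± 0.20 and 1.47 ± 0.20. A rise of aryl hydrocarbon receptor targets is a candidate explanation, since 5 of 5 tested members were called higher in all 3 comparisons. The list was written after its members had been seen and so cannot decide this explanation. Of 10 tested NRF2 targets 4 were called higher in all 3 comparisons and 6 were not, so a rise of the group stays open, with Osgin1 and Srxn1 among those that rose on every surface, and Nqo1 is on both lists.

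Notch pathway genes went both ways. Of 13 tested members 7 were called higher in all 3 comparisons, while Rbpj, the DNA-binding partner of Notch, fell by 0.81 ± 0.19 and 0.98 ± 0.19 on fibronectin and laminin, and Lfng, a Notch-modifying glycosyltransferase, fell by 0.76 ± 0.12 and 0.87 ± 0.12 on fibronectin and uncoated dishes; both were called lower in all 3 comparisons. The receptor gene Notch2, at 373 CPM in suspension, was called lower on fibronectin and laminin, by 0.40 ± 0.10 and 0.61 ± 0.10. On uncoated dishes it fell by 0.32 ± 0.10 and passed with the block (edgeR, adjusted p = 0.0181). Hey1 had 3 counts over the suspension libraries and 36, 60 and 48 on fibronectin, laminin and uncoated dishes. The ratios were 11.5, 18.9 and 16.6, with lower counting bounds of 3.65, 6.16 and 5.36. A rise of Notch signalling in plated cells may account for these members, which were seen before the list was written. A fall in suspension, or a difference in time or serum, which the labels do not settle for suspension, would give the same values, so this stays open.

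The attached replicate 3 libraries lay apart from replicates 1 and 2 of their groups. Depth and ribosomal RNA are argued against, since 3 of the 3 libraries lay inside the range of the other 9 for both. A difference of the whole batch is argued against for suspension 3, whose deviations correlated at 0.0676 at most with those of the attached replicate 3 libraries, against 0.752 to 0.853 among these. A stronger response to attachment is argued against as the whole source, since the shift correlated with the response at 0.383 after correction for reliability (0.253 before), where a shift along the response needs a value near 1. The labels give the same 2 h protocol for every library and record no departure from it in batch 3. What set these dishes apart, such as handling or the actual time after plating, stays open.

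More genes were called higher than lower in attached cells. The attached replicate 3 libraries are a candidate source of this, since at most 46.5% of the calls were higher in any of the 3 comparisons once batch 3 was left out. With all attached replicate 3 libraries left out and suspension 3 kept, 49.0% (fibronectin), 46.4% (laminin) and 45.4% (no coating) were higher. With only fibronectin 3, laminin 3 or no coating 3 left out, 68.0%, 55.9% and 64.1% were higher in the comparison of that group. Leaving out that single library therefore did not make the split even. Library scaling stays open: with library size only at most 54.8% of the calls were higher, which is closer to an even split without reaching it.

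Splits of 3 against 3 libraries number 10, so no share under 0.1 is possible. The counts of genes were 969, 1905, 1261, 15 and 18 for fibronectin, laminin and no coating against suspension, laminin against fibronectin and fibronectin against no coating, with the real split as 1 of 10 in each and a highest other count of 0. The other splits mix libraries of the 2 conditions within a group. A real difference then adds to the spread and lowers their calls, so these low counts do not measure chance. For laminin against no coating all 10 splits gave 0. In each comparison 4 of the 10 splits part all 3 batch pairs, the real split among them. The lists passed by camera were 6, 7, 9, 9, 6 and 2 in the same order, and the other splits reached 6, 5, 6, 7, 5 and 7, with 5, 1, 1, 1, 1 and 4 of the 10 splits as large. For the test of any difference among the 4 groups, 3 of 100 divisions of the 12 libraries called at least as many genes as the real 969. These divisions ignore the batch, whereas each real group holds 1 library of every batch. The other such divisions called 1018 with the suspension libraries kept together and 3666 with fibronectin 3, laminin 3 and no coating 3 together. The 3666 calls point to the structure of the replicate 3 libraries, and the real division gave 3190 with the block. Among 100 divisions that keep 1 library of every batch in each group, the real one gave the most calls, 969 against 665 at most in the others, and 3190 against 2501 with the block. The other division with 665 calls also kept the suspension libraries together.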
